A study of Mus musculus with 6 samples.

How the data were processed

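The series holds RNA sequencing of mouse hippocampus, with 3 control and 3 lidocaine libraries of young animals used here. Per the labels' protocols, total RNA was extracted with an RNeasy kit and libraries were made with a SMARTer mRNA kit. The submitters' processing notes name the genome build mm10. The aligner, the counting program and the gene annotation are not given in the sources used here. The deposited table lists 22050 genes, all under rat Ensembl identifiers, and 72.8% of its symbols, letter case aside, also occur in the mouse gene table supplied for this work. Which species' reads or annotation lie behind the values could not be settled from the table, so no coordinates were used. If mouse reads were counted on rat genes, counts would depend on how alike the genes are in the 2 species.

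The deposited table gives, per gene and library, an estimated count and an FPKM value (fragments per kilobase of transcript, scaled to the library's mapped fragments), per the file headers. The estimated counts deposited by the authors are not normalised, and 30.4% of all genes (44.8% of tested ones) have a fractional count in at least 1 library. The FPKM values deposited by the authors are scaled for length and depth and were used for 1 alternative. Samples were grouped by their titles, and the table's columns were matched to them by the group's initial and the replicate number. Totals ranged from 13887604 to 16984995 counts per library, and 16925 genes had a count above 0 in at least 1 library. With 3 libraries per group, a permutation test cannot give p under 0.1.

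Estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr on the group, which left 13408, and scaled by TMM factors, which ranged from 0.991 to 1.009. Lidocaine and control were compared with edgeR 4.0.16 (quasi-likelihood F-test, robust, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and calls at an adjusted p under 0.05. The biological coefficient of variation was 17.8%. Standard errors and 95% intervals of fold changes were derived from the F statistic. DESeq2 1.42.0, limma-voom (limma 3.58.1) and limma on log2(FPKM + 1) were run as alternatives. The median log2 fold change of all tested genes was 0.00 under TMM, under RLE size factors and with no scaling factor.

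Before the data were examined, 42 gene lists were fixed, covering microglia and reactive astrocytes, synapses and ion channels, stress and activity responses, RNA quality, other cell types, and hippocampal subfields and neighbouring regions. Of their 744 entries, 685 matched 1 row of the table, 7 of them through rat symbols added after the table was seen. The 41 lists with at least 3 tested genes were tested with camera (limma, preset correlation of 0.01, two-sided, log2 CPM with a prior count of 2), with an estimated correlation and with fry. The remaining list, of sex-linked genes, was a check of the labels. Some genes belong to more than 1 list, as Dcn does to the meningeal and CA1 lists.

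Genes named in the text follow a rule fixed before the data were examined. It took the 12 genes with the largest fold change per direction among called genes with separated groups and a mean of at least 1 CPM, and up to 4 called members per list. Of 6 study lists and the sodium channel list with none called, it took the 2 members with the smallest p. Because fewer than 10 genes were called, it also took the 10 genes with the smallest p, and finally Gfap, Aif1, C3, Tnf, Il1b, Dlg4 and Syp. Other genes named as examples from lists, and Ccn1, were chosen after their values were seen. Some genes that the rule or a count would name are not reported here.

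Alternatives changed the scaling, the test, the filter, the threshold and the correlation setting, added the replicate number as a block, or left out each library in turn. Tests restricted to genes with whole counts or with no count of 0, the test on FPKM, fry's test of change in either direction, and list tests without scaling factors or without mitochondrially encoded genes were added after seeing the data. No pair of libraries agreed within sampling noise: chi-square per degree of freedom was 4.77 to 11.91 over all pairs.

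The test was tried on simulated data with the real means, library sizes and dispersions, in 10 simulations of 13408 genes, each with 200 changed genes. edgeR recovered 3% of genes changed 1.25-fold, 31.8% at 1.5-fold, 64.2% at 2-fold and 83.4% at 4-fold. These shares hold for 200 changed genes, since the Benjamini-Hochberg cut is stricter where fewer genes change. Of 1028 calls, 112 (10.9%) were unchanged genes, more than the 5% that the threshold aims at. Camera gave p under 0.05 in 10 of 10 simulations for a list of 19 independent genes shifted by -0.3 on the log2 scale, and for 5 of 200 unshifted lists. Simulated genes were independent of each other, so this does not cover lists whose genes vary together.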

Results

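Messenger RNA of the hippocampus, a brain region needed for forming memories, was sequenced in 6 libraries from young mice, 3 of control animals and 3 of animals given repeated injections of lidocaine. Lidocaine is a local anaesthetic that blocks voltage-gated sodium channels. The series' design also has old mice, which were not analysed here, and the comparison made here asks which hippocampal genes differ with lidocaine in young animals. Estimated counts summed to 14488273, 15990264 and 13887604 in control libraries 1, 2 and 3, and to 16984995, 16013017 and 16045172 in lidocaine libraries 1, 2 and 3. The labels name the mouse, whereas all 22050 rows of the table carry rat Ensembl identifiers and 19832 carry rat gene symbols. Genes are therefore named as the table names them, with no coordinates, and the species of the reference behind the values stays open. Column names match the sample titles by a group initial and a number and do not state age. The Y-linked genes Kdm5d (68.3 to 78.5 CPM, counts scaled to library size) and Eif2s3y (40.1 to 47.6 CPM) were present in all 6 libraries. The labels do not say whether each library came from a separate animal, so p-values measure the spread between these libraries.

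Few genes separated lidocaine from control hippocampus. Rbm39, an RNA-binding protein of splicing, and Ndst2, an enzyme that modifies heparan sulfate, were the 2 genes called lower with lidocaine, and 0 genes were called higher. Rbm39 was listed at 182, 119.6 and 103 estimated counts in the control libraries and at 0 in all 3 lidocaine libraries. Ndst2 was listed at 75.2, 62.3 and 64.4 counts in the controls and likewise at 0 with lidocaine. Each had a Benjamini-Hochberg-adjusted p of 0.0302 in edgeR's quasi-likelihood test over 13408 genes. Both have fractional counts, as genes that share reads with others do, so an exact 0 can be a failed estimate and no fold is given.

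The 8 genes with the next smallest p did not pass in edgeR, the main test, but DESeq2, an alternative, called all 8, with Benjamini-Hochberg-adjusted p from 1.68e-09 for Extl3 to 0.00421 for Cul2. Extl3, which starts heparan sulfate chains, was listed at 153, 72.9 and 87.8 counts in the controls and at 0 in all 3 lidocaine libraries, and edgeR with no filter called it (Benjamini-Hochberg-adjusted p = 0.045). Mcrip1 was listed at 0 in all 3 controls and at 153, 61.6 and 162 counts with lidocaine. Adarb2, an RNA-editing enzyme family member of the brain, was likewise at 0 in the controls and at 90.7, 44.2 and 29.7 counts with lidocaine. Of the genes with counts in every library, Vps33a, a part of the machinery that fuses endosomes with lysosomes, averaged 25.6 ± 3.04 CPM in controls and 47.7 ± 1.89 CPM with lidocaine (SD, n = 3 each). Its log2 fold change was 0.90 ± 0.10 (SE), with an adjusted p of 0.0986 in edgeR with Benjamini-Hochberg adjustment. Plekhg3 had a log2 fold change of -1.44 ± 0.18 (edgeR, Benjamini-Hochberg-adjusted p = 0.129). Col6a1, a collagen VI chain, had -0.99 ± 0.16, the actin-binding protein Afap1 had 1.46 ± 0.24 and the ubiquitin ligase scaffold Cul2 had 0.88 ± 0.15 on the same scale. Their adjusted p-values were 0.447, 0.447 and 0.457 in edgeR with Benjamini-Hochberg adjustment.

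At an unadjusted p under 0.05, edgeR gave 585 genes, 268 higher and 317 lower with lidocaine, where 670 would be expected by chance. The 3 values of a group all lay above those of the other in 1338 genes, 10% of those tested, which is the share that chance gives for 3 against 3. limma-voom called 0 genes higher and 2 lower, whereas DESeq2 called 14 higher and 9 lower, and limma on FPKM called 0 higher and 1 lower. Of the 23 genes DESeq2 called, 20 had fractional counts and 9 were listed at 0 in 3 or more libraries. The 3 with whole counts, singled out after their values were seen, were Ccn1, Igf2 and Col6a1. Ccn1, a secreted matrix protein induced by stretch and growth factors, was counted 34, 17 and 41 times in the controls and 181, 164 and 352 times with lidocaine. Its log2 fold change was 2.76 ± 0.46 in edgeR (Benjamini-Hochberg-adjusted p = 0.551) and 2.77 in DESeq2 (adjusted p = 9.99e-07).

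Neither Rbm39 nor Ndst2 passed edgeR's test without control library 1 (Benjamini-Hochberg-adjusted p = 0.0764 and 0.17), control 2 (0.114 for both), control 3 (0.256 for both) or lidocaine 2 (0.0568 for both). With only genes whose counts are whole, or only genes above 0 in all 6 libraries, edgeR called 0 genes, with 370 and 587 genes at an unadjusted p under 0.05.

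**Figure D1:**
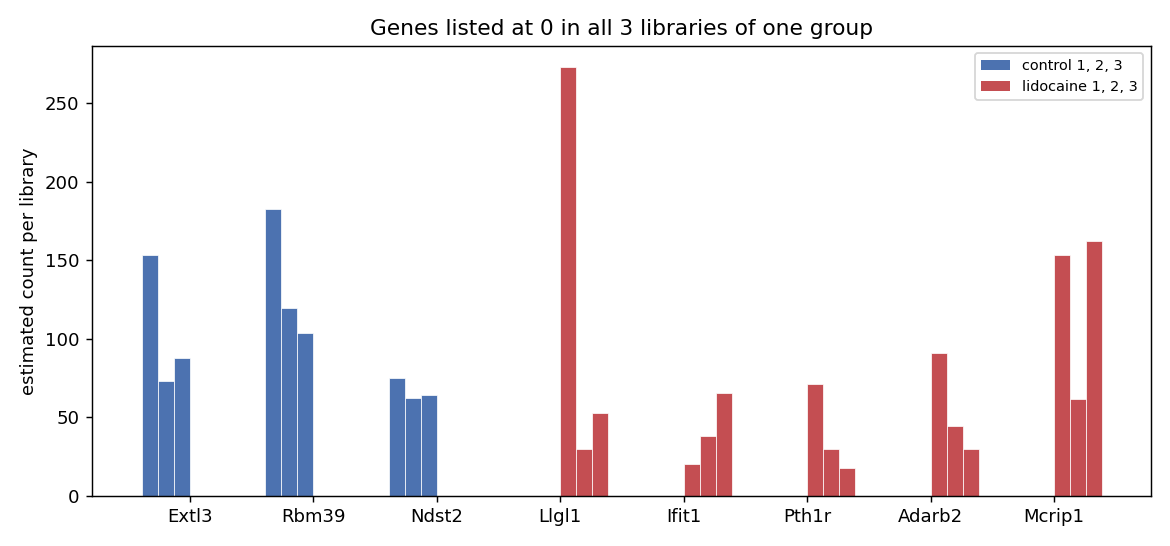
Estimated counts (y axis) of the 8 genes with a mean count of at least 10 that were listed at 0 in all 3 libraries of 1 group and above 0 in all 3 of the other, with 1 bar per library (control blue, lidocaine red). Extl3, Rbm39 and Ndst2 were at 0 with lidocaine, and Llgl1, Ifit1, Pth1r, Adarb2 and Mcrip1 were at 0 in the controls.

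Genes of microglia, the immune cells of the brain, and of reactive astrocytes, glia that respond to injury, were examined because the study's title speaks of both. None of the tested members of these lists was called by edgeR, over all genes or adjusted over the list alone, apart from Ifit1 in the interferon list. Gfap, the main astrocyte filament protein, averaged 1648 ± 120.3 CPM in controls and 1749 ± 116 CPM with lidocaine (SD, n = 3 each), a log2 fold change of 0.09 ± 0.07 (SE). Aif1, the microglial marker known as Iba1, averaged 7.21 ± 1.05 and 7.66 ± 0.34 CPM, a log2 fold change of 0.09 ± 0.17. The complement component C3, used as a marker of A1 astrocytes, averaged 28.0 ± 6.01 and 23.7 ± 4.24 CPM, a log2 fold change of -0.24 ± 0.19, which ranged from -0.37 to -0.06 when each library was left out in turn. Tnf was listed at 0 counts in all 6 libraries and Il1b at 0 to 2, so changes in these cytokines were not detectable at this depth.

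Of the 25 genes in the activated microglia and inflammation list, only 12 passed the count filter and were tested. The others, among them Tnf, Il1b, Il6 and Ccl2, are not covered by the list's result. Of the 12, 9 had a negative and 3 a positive fold change, and the list's median log2 fold change was -0.15. It was not called by limma's camera (Benjamini-Hochberg-adjusted p = 0.263), and its adjusted p was 0.954 with an estimated correlation. With whole-count genes alone, a setting chosen after seeing the data, camera called it lower (Benjamini-Hochberg-adjusted p = 0.0292). Its members with the smallest p were Spp1, osteopontin, at -1.25 ± 0.38 on the log2 scale with 12, 19 and 21 counts in controls and 8 in each lidocaine library, and the lipoprotein lipase Lpl at 0.16 ± 0.07. The mean of the list lay between -0.25 and -0.17 in the lidocaine libraries and between -0.05 and 0.08 in the controls. A two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 allows.

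Among the astrocyte lists, the A1 list had a median log2 fold change of 0.03 over 8 genes, the A2 list 0.24 over 7 and the pan-reactive list -0.22 over 10. Camera with Benjamini-Hochberg adjustment gave adjusted p-values of 0.926, 0.592 and 0.495. The A1 members with the smallest p were the glucocorticoid-induced Fkbp5 at 0.19 ± 0.08 and Ggta1 at -0.34 ± 0.18. Those of the A2 list were Ptgs2, cyclooxygenase 2, at -0.25 ± 0.13 and Emp1 at 0.33 ± 0.19, and those of the pan-reactive list were the small heat shock protein Hspb1 at -0.69 ± 0.27 and Aspg at -0.80 ± 0.41. Homeostatic microglia genes had a median of 0.04 over 17 genes, general astrocyte genes 0.00 over 17 and complement genes -0.02 over 15, and camera called none of these 3 lists. The interferon list had a median of 0.06 and a mean of 0.53 over 18 genes. Setting Ifit1 at the bound that a floor of 3 counts over the control group allows, 37.3-fold, could not move this median. That bound still lies above the list's upper quartile of 0.46 on the log2 scale. Among members with no count of 0 the median was 0.03 (0.025). Ifit1, an interferon-induced antiviral gene, was listed at 0 in all 3 controls and at 20, 38 and 65.7 counts with lidocaine. It passed when adjusted over the list alone (adjusted p = 0.00677) and not over all genes (adjusted p = 0.457), both in edgeR with Benjamini-Hochberg adjustment.

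**Figure D2:**
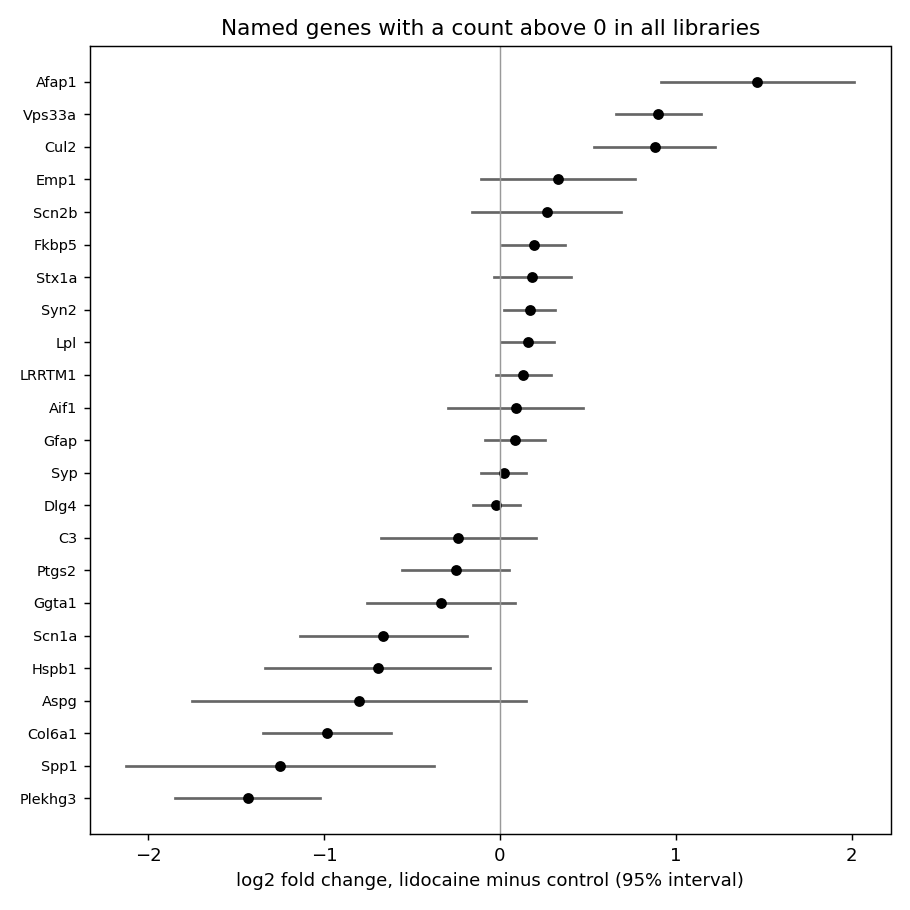
Log2 fold change of lidocaine over control (x axis) for 23 named genes with a count above 0 in all 6 libraries, as edgeR's estimate (point) with its 95% interval (line). None passed the test, and Gfap (0.09), Aif1 (0.09), Dlg4 (-0.02) and Syp (0.02) lie next to 0.

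Synaptic genes lay close to their control levels. Dlg4, which encodes the postsynaptic scaffold PSD-95, averaged 1571 ± 29.6 CPM in controls and 1550.3 ± 95.3 CPM with lidocaine (SD, n = 3 each), a log2 fold change of -0.02 with a 95% interval from -0.15 to 0.12. Syp, the synaptic vesicle protein synaptophysin, averaged 467 ± 20.8 and 474 ± 11.7 CPM, a log2 fold change of 0.02 with an interval from -0.11 to 0.15. The sign of both, and of Aif1, turned when 1 library was left out. The presynaptic list had a median log2 fold change of 0.02 over 23 genes, the glutamatergic postsynaptic list 0.02 over 28 and the list of GABA receptors and the inhibitory synapse 0.01 over 14. Camera called none of the 3 (Benjamini-Hochberg-adjusted p = 0.739, 0.855 and 0.878). The presynaptic members with the smallest p were the vesicle protein Syn2 at 0.17 ± 0.06 and the fusion protein Stx1a at 0.19 ± 0.09. On the postsynaptic side LRRTM1, a synapse-organising protein, had 0.13 ± 0.07. All 3 had an adjusted p of 0.995 in edgeR with Benjamini-Hochberg adjustment.

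Voltage-gated sodium channels, the target of lidocaine, were not called as a list. Over 13 genes the median log2 fold change was -0.03, with 5 positive and 8 negative (camera, Benjamini-Hochberg-adjusted p = 0.845). Scn1a, the channel prominent in inhibitory interneurons, averaged 110.2 ± 14.8 CPM in controls and 69.6 ± 18.0 CPM with lidocaine (SD, n = 3 each). Its log2 fold change of -0.66 ± 0.20 (SE) did not pass (edgeR, Benjamini-Hochberg-adjusted p = 0.995), and its counts are fractional. Scn2a, a main channel of excitatory neurons, averaged 914 ± 34.8 CPM in controls and 913 ± 14.2 CPM with lidocaine, and the auxiliary subunit Scn2b had a log2 fold change of 0.27 ± 0.18, with 0.13 (0.125) as the lowest and 0.46 as the highest value when each library was left out. Potassium and calcium channel genes had a median of -0.03 over 23 genes (camera, Benjamini-Hochberg-adjusted p = 0.577).

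Of 41 gene lists with at least 3 tested members, camera called 4, of which the oligodendrocyte and myelin list had the smallest p and the meningeal list the largest median shift. Oligodendrocyte genes, which make the insulating sheath of axons, had a negative fold change in 18 of 19 members and a median log2 fold change of -0.33 (camera, Benjamini-Hochberg-adjusted p = 2.2e-09; adjusted p = 0.954 with an estimated correlation). The heat shock list, chaperones that refold proteins, had negative fold changes in 12 of 13 members and a median of -0.22 (adjusted p = 0.00168 by camera with Benjamini-Hochberg adjustment; adjusted p = 0.954 with an estimated correlation). All 13 mitochondrially encoded genes had negative fold changes, with a median of -0.28 and the same pair of values (camera, Benjamini-Hochberg-adjusted p = 0.00168; adjusted p = 0.954 with an estimated correlation). Meningeal fibroblast genes, which mark the membranes around the brain, had positive fold changes in 12 of 13 members and a median of 0.34 (camera, Benjamini-Hochberg-adjusted p = 0.00192; adjusted p = 0.954 with an estimated correlation). Without adjustment, 6 lists had p under 0.05 by camera, 0 with an estimated correlation and 1 by fry's directional test, and after adjustment both of the latter called 0 lists.

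No member of the oligodendrocyte list was called by edgeR, and 0 were called adjusted over the list alone, while 8 had an unadjusted p under 0.05, all with negative fold changes. Mbp, myelin basic protein, averaged 5533 ± 186 CPM in controls and 4221 ± 564 CPM with lidocaine (SD, n = 3 each), a log2 fold change of -0.39 ± 0.09 (edgeR, Benjamini-Hochberg-adjusted p = 0.995; DESeq2, adjusted p = 0.0327). Mal had -0.49 ± 0.18 and Opalin -0.43 ± 0.13. Oligodendrocyte precursor genes had a median of -0.10 over 10 genes and were not called (camera, Benjamini-Hochberg-adjusted p = 0.878), with the progenitor marker Cspg4 at 0.25 ± 0.08 and the lineage factor Olig1 at -0.14 ± 0.06. The oligodendrocyte list mean, relative to the mean of the controls, was -0.13, 0.11 and 0.02 in controls 1 to 3 and -0.51, -0.37 and -0.09 in lidocaine 1 to 3, so that control 1 lay below lidocaine 3. A two-sided exact permutation test of these means gave p = 0.2, and camera called the list without each of the 6 libraries in turn. The mitochondrially encoded genes took 2.81%, 2.42% and 2.66% of the counts of controls 1 to 3 and 2.82%, 2.21% and 2.20% of lidocaine 1 to 3.

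Among heat shock genes, Hspa1b, an inducible HSP70, averaged 499 ± 196 CPM in controls and 270.4 ± 38.9 CPM with lidocaine (SD, n = 3 each), a log2 fold change of -0.88 ± 0.33. Its near-identical copy Hspa1a shares its reads, so the value is uncertain. Dnajb1 had -0.24 ± 0.10 and Hsph1 -0.22 ± 0.10, whereas the constitutive chaperone Hspa8 had 0.04 ± 0.14. Heat shock list means were 0.24, 0.05 and -0.29 (-0.285) in controls 1 to 3 and -0.12, -0.21 and -0.41 in lidocaine 1 to 3, so that control 3 lay below lidocaine 1 and 2, and a two-sided exact permutation test gave p = 0.3. The heat shock list was not called without control 1 (adjusted p = 0.144), control 2 (adjusted p = 0.0541) or lidocaine 3 (adjusted p = 0.216), all by camera with Benjamini-Hochberg adjustment. Mt-atp6 had a log2 fold change of -0.39 ± 0.23 and Mt-co1, at 18472 ± 459 CPM in controls and 17624 ± 1973 CPM with lidocaine (SD, n = 3 each), -0.07 ± 0.08. Camera with Benjamini-Hochberg adjustment did not call the mitochondrial list without control 1 (adjusted p = 0.128), lidocaine 2 (adjusted p = 0.168) or lidocaine 3 (adjusted p = 0.216). Its means were 0.22, -0.27 and 0.04 in controls 1 to 3 and 0.10, -0.51 and -0.47 in lidocaine 1 to 3, so that lidocaine 1 lay above controls 2 and 3, and the same exact permutation test gave p = 0.3. Genes for nuclear-encoded oxidative phosphorylation had a median of 0.02 over 27 genes and cytosolic ribosomal protein genes -0.02 over 27, and neither list was called.

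In the meningeal list, Igf2, a growth factor made by the meninges and choroid plexus, averaged 25.8 ± 0.15 CPM in controls and 38.2 ± 5.04 CPM with lidocaine (SD, n = 3 each), a log2 fold change of 0.57 ± 0.11. It passed when adjusted over the list alone (adjusted p = 0.0114) and by DESeq2 over all genes (adjusted p = 0.0316), but not in edgeR with Benjamini-Hochberg adjustment over all genes (adjusted p = 0.619). Aldh1a2, the retinoic acid enzyme of the meninges, had 0.70 ± 0.30 and the collagen Col3a1 0.48 ± 0.23. List means were -0.02, 0.04 and -0.02 in the controls and 0.54, 0.19 and 0.17 in lidocaine 1 to 3, where a two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 allows. Without lidocaine 1, camera did not call the list (Benjamini-Hochberg-adjusted p = 0.137).

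**Figure D3:**
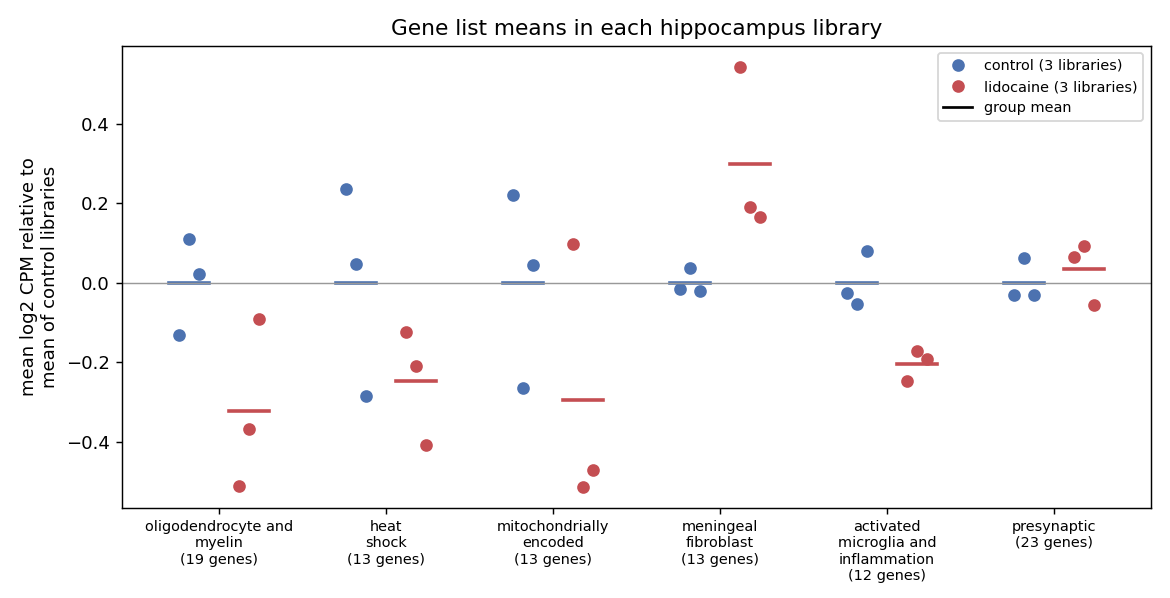
Mean over the genes of 6 lists of log2 CPM minus the mean of the control libraries (y axis), with 1 point per library (control blue, lidocaine red) and a line at each group mean. The oligodendrocyte list reaches -0.51 in lidocaine 1 and the meningeal list 0.54 in the same library, while the presynaptic points lie between -0.06 and 0.09.

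Markers of other cells and of neighbouring tissue were compared in the same way, and camera called none of these lists. Median log2 fold changes were 0.00 for interneurons (14 genes), -0.04 for endothelial and mural cells (16), 0.12 for choroid plexus (7), 0.09 for ependyma (6), -0.16 for erythrocytes (6) and 0.04 for peripheral immune cells and border macrophages (5). Choroid plexus content was low, with Ttr, its most abundant transcript, at 1.35 to 8.78 CPM. For the parts of the hippocampus, dentate gyrus granule cells had a median of 0.00 (9 genes), CA1 pyramidal cells -0.06 (8) and CA2 and CA3 pyramidal cells -0.01 (12). Ndst4, a heparan sulfate enzyme in the CA1 list, averaged 14.4 ± 0.80 CPM in controls and 9.05 ± 0.63 CPM with lidocaine (SD, n = 3 each). Its log2 fold change of -0.67 ± 0.13 passed in edgeR when adjusted over the list alone (Benjamini-Hochberg-adjusted p = 0.00622) and not over all genes (adjusted p = 0.579). Regions next to the hippocampus had medians of -0.07 for thalamus (13 genes), -0.02 for striatum (11), -0.09 for neocortex (14) and -0.19 for septum, hypothalamus and hindbrain (8). In the last of these, 7 of 8 genes were negative and the list means lay between -0.34 and -0.14 in the lidocaine libraries and between -0.06 and 0.05 (0.045) in the controls, with a two-sided exact permutation p of 0.1, the smallest possible. It is the 1 list with an unadjusted p under 0.05 by fry's directional test (Benjamini-Hochberg-adjusted p = 0.682). In all, 3 of the 41 lists separated the groups in this way, no more than the 10% that chance gives for 3 against 3.

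Response lists were not called by camera either, heat shock aside. Activity-induced immediate early genes had a median of 0.07 over 27 genes, of which 8 had an unadjusted p under 0.05, 6 with positive and 2 with negative fold changes. Among these 8, Btg2 had 0.53 ± 0.16, Fos 0.53 ± 0.22, Nr4a3 -0.17 ± 0.06 and Inhba -0.45 ± 0.15. In fry's test of change in either direction, chosen after seeing the data, this list had a Benjamini-Hochberg-adjusted p = 0.0748 over the 41 lists and was not called. That test called 3 lists, interferon, oxidative stress and CA1, each with a Benjamini-Hochberg-adjusted p of 0.00831 by fry. Their members with the smallest p were Ifit1, the glutathione transferase Mgst1 at 0.83 ± 0.22, and Ndst4, and in the oxidative stress and CA1 lists this was the only member with an unadjusted p under 0.05. Glucocorticoid-responsive genes had a median of 0.03 over 18 genes, the circadian clock 0.02 over 15, apoptosis -0.02 over 18 and endoplasmic reticulum stress -0.03 over 16. Oxidative stress response genes had 0.03 over 14, cholesterol biosynthesis 0.00 over 19 and neural progenitor and immature neuron genes 0.01 over 13. Median, mean and camera's direction did not share a sign in 11 lists, among them the A1, astrocyte, interneuron, apoptosis, choroid plexus and hippocampal subfield lists other than CA1. Adjusted over the list alone, edgeR called 1 gene in each of the interferon, meningeal and CA1 lists and 0 in the other lists.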

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

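The count of genes called higher with lidocaine was 0 in the main test and stayed at 0 under RLE size factors, total count only, limma-voom, both other count filters and a fold of at least 1.5. DESeq2 gave 14 higher and 9 lower, and an adjusted p under 0.1 gave 1 higher. The count of genes lower, 2 in the main test, was 0 with whole-count genes, 0 with no zero estimates and 1 with FPKM, 3 settings chosen after seeing the data. Restricting the genes removes Rbm39 and Ndst2 from the test by construction, since both have fractional counts and zeros; the cause of the other differences was not tested. Leaving out each library in turn gave 0 to 1 genes higher and 0 to 6 lower. The 6 came without lidocaine 1, while Rbm39 and Ndst2 were lost without any 1 control or lidocaine 2.

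Deviations of same-numbered libraries from their group means correlated at 0.045, 0.027 and -0.001, and those of differently numbered ones at -0.043 to 0.017. Deviations from a mean of 3 libraries make each library's covariances with the other group sum to 0, but do not hold single correlations near 0. The same-numbered values thus show no strong pairing over all tested genes. A weak pairing, or one of few genes, stays open. With the replicate block, 0 genes were called higher or lower and 4 lists by camera, the same 4. The count of called lists was 4 in the main test, 0 with an estimated correlation, 0 with fry, 3 with fry mixed (change in either direction, chosen after seeing the data; none of the same 4), and 2 to 5 when each library was left out, with 2 without control 1 or lidocaine 3. The oligodendrocyte list was called in each of these 6 settings, the meningeal list in all but that without lidocaine 1.

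Of 319 alternative values of 29 named genes, 8 gained a call, 10 lost it and 4 turned sign. The 8 are the DESeq2 values of Extl3, Vps33a, Plekhg3, Mcrip1, Adarb2, Col6a1, Afap1 and Cul2. The 10 are values of Rbm39 and Ndst2 without 1 library or with the replicate block, which costs degrees of freedom. In 12 of the 29 genes, by a count added after seeing the data, leaving out 1 library moved the value by over 1.5 times or past 0. Besides C3 and Scn2b, they include Gfap (0.035 to 0.139), Hspb1 (-0.92 to -0.45) and Ptgs2 (-0.39 to -0.11). Emp1 (0.22 to 0.51), Stx1a (0.10 to 0.28) and LRRTM1 (0.08 to 0.18) are also among them. The 4 values that turned sign lay in genes near 0 and came by leaving out 1 library. Aif1 ranged from -0.02 (-0.015) without control 2 to 0.20 (0.195), Dlg4 from -0.07 (-0.069) to 0.01 (0.011) without lidocaine 2 and 0.006 without lidocaine 1, and Syp from -0.01 (-0.013) without control 1 to 0.05 (0.051). The cause was not tested. Pseudocount and low-value filters planned for a table without counts were not run, since the table holds counts. At this depth and n, simulations with 200 changed genes each recovered 31.8% of 1.5-fold changes, so smaller differences were mostly not detectable. The Benjamini-Hochberg cut is stricter where fewer genes pass, and only 2 were called here. Recovery in these data may thus be lower at every fold, and larger differences may have been missed too.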

Other observations

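The tests of reads shared between genes, of other splits for the gene calls and for the oligodendrocyte list, and of correlated oligodendrocyte genes were chosen only after the results they bear on were seen. KEGG pathways in the deposited annotation gave no called set: of 326 pathways with 10 to 300 tested genes, camera with Benjamini-Hochberg adjustment called 0, with 10 at an unadjusted p under 0.05, and with an estimated correlation 0 and 0. The proteasome, which degrades proteins, came first, with 38 of 45 genes positive and a median log2 fold change of 0.06 (camera, Benjamini-Hochberg-adjusted p = 0.302; adjusted p = 0.997 with an estimated correlation). Heparan sulfate and heparin biosynthesis was not called either, with 10 of 22 genes positive, 12 negative and a median of -0.015. Camera gave it the same 2 adjusted p-values, 0.302 and 0.997.

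Single libraries stood apart in some genes or gene groups. Interferon genes were highest in lidocaine 3, with a list mean of 0.77 against -0.28 to 0.20 in the other 5 libraries. Irf7, a regulator of the interferon response, was counted 223 times there and 35 to 100 times elsewhere, and Ifit3 109 times against 19 to 58. Wfs1, a marker of CA1 pyramidal cells, was counted 5555 times in lidocaine 2 and 9646 to 13397 times in the others. The CA1 list as a whole did not set this library apart, with means of -0.20 in lidocaine 2 and -0.22 in lidocaine 3. On the first principal component (22.1% of the variance) lidocaine 3 lay at 48.5 and the other 5 libraries between -16.5 and 1.7. Lidocaine 1 and 2 lay at 1.7 and -6.1, and controls 1 to 3 at -16.5, -13.6 and -14. This component thus separated the groups, as chance does in 10% of cases for 3 against 3. The second (21%) set control 1 apart at 40.5, with the others between -25 and 9.5. Even the fifth component held 18.3% of the variance, so no component dominated.

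Rbm39 and Ndst2 were listed at 0 in every lidocaine library, and 2 technical readings of this were tested. If zeros come from reads shared between genes, genes at 0 in 1 library and at 50 or more in another should have fractional counts more often than others, and 183 of 183 such tested genes did, against 44% of the 13225 others (Fisher's exact test, two-sided, p = 2.7e-65). They include ribosomal protein genes that every cell uses, with Rpl30 at 0 in lidocaine 1 and 185 to 499.8 counts elsewhere, and Rps10 at 0 in control 3. Genes at 0 throughout 1 group and above 0 throughout the other numbered 8 for the real groups and up to 8 for the 9 other splits of the libraries, consistent with on and off estimates that fall along the groups by chance. For the gene calls, 2 of the 10 splits gave as many as the real 2, with 3 as the highest other, and 10 splits are too few for a share under 0.05; an effect of lidocaine on these genes stays open, as untested.

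Lower oligodendrocyte genes were weighed against 3 readings. A shift peculiar to the genes picked for the list is argued against, under the preset correlation only. The check used markers of the same cells in the same libraries, so it does not bear on chance differences between libraries. A second oligodendrocyte list with no gene in common had a median of -0.15 (-0.148) over 24 genes, 20 of them negative (camera p = 0.000283, and p = 0.199 with an estimated correlation), including Evi2a at -0.37 ± 0.10 and Ninj2 at -0.52 ± 0.18. Different amounts of white matter in the dissected tissue cannot be told apart from a difference between the groups: the estimated correlation of the list was 0.606, but heat shock (0.844) and mitochondrially encoded genes (0.874) were higher, so that co-expression alone decides nothing. For the difference between the groups, the prediction set beforehand was that all 3 lidocaine list means would lie below all controls. Any overlap was to count against it. Only 2 of the 3 did, so the prediction failed. The third overlapped by less than the control SD of 0.12, but this margin was not in the prediction. With 3 libraries per group the overlap alone does not exclude a difference. Camera also called this list under 4 of the 9 other splits, with an adjusted p of 4.71e-10 for control 1, lidocaine 1 and lidocaine 2 against the rest, smaller than the real 2.2e-09 (both Benjamini-Hochberg-adjusted), and over all lists 8 of the 10 splits gave as many called lists as the real 4, with 11 as the highest other and too few splits for a share under 0.05.

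Higher meningeal genes could come from more meninges left on the lidocaine tissue, which was predicted to raise other meningeal genes too. A second meningeal list with no gene in common had a median of -0.02 over 17 genes (quartiles -0.20 and 0.02). Camera gave it an unadjusted p of 0.557, so the prediction was not met. Cemip was at 0.70 ± 0.23, but Foxc1, a transcription factor of the meninges, was at -0.20 ± 0.22 and Col6a2 at -0.29 ± 0.17. The most abundant member, Ptgds, averaged 204 CPM in controls and 201.5 with lidocaine, though it and Cdh11 are also made by cells of the hippocampus. Nupr1, Postn and Fbln2 averaged only 0.7, 1.2 and 1.2 CPM in controls. Extra meninges would raise a gene only by the share of its signal that comes from meninges, so the test cannot decide. More meninges on the lidocaine tissue stays open, and so does a change of these genes with lidocaine, which was untested.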
